A study of Mus musculus with 8 samples.

How the data were processed

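RNA was sequenced from mouse fibro-adipogenic progenitors (FAPs), the mesenchymal cells of skeletal muscle that can become adipocytes or matrix-producing fibroblasts. Per the labels, the cells came from uninjured tibialis anterior, gastrocnemius and quadriceps muscles of wild-type male mice, were kept in culture for 48 h, and then received vehicle or melatonin for 24 h. The labels give 4 biological replicates per condition, so 8 libraries in all. No melatonin concentration is given in the sources used here. The labels' extraction protocol names longissimus dorsi as the source of the RNA, which differs from the 3 muscles named elsewhere in the labels, and this was left unresolved. The strain is given as C57BL/6 in one place and C57BL/6J in another.

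The authors deposited a table of counts, with whole numbers for 20781 Ensembl genes in 8 columns. One set of columns carries the prefix of the melatonin group, and the other, prefixed as a control, was read as vehicle because only one other group exists. Every gene in the deposited table of counts has a total of at least 11 over the 8 libraries, so genes with fewer counts were not analysed here. Per the submitters' processing notes, the tools were FastQC 0.11.2, Trimmomatic 0.36, HISAT2 2.0, bedtools 2.26.0, StringTie 1.3.3b and DESeq2 1.12.4, with genome build mm10. The program that made the counts, the gene annotation release and the use of strand are not given in the sources used here. Reads shared by paralogs or by overlapping genes may therefore have been split or assigned in ways that the table does not show, and a gene cannot be told from an antisense partner. This holds for the class I histocompatibility genes, the Gsta family, the histone genes, Saa3, Mmp1b and the Ifit3 pair. Symbols and positions came from GENCODE release M21 on GRCm38, the assembly also called mm10, in which 20720 of the 20781 gene IDs were found and 61 were not.

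Library totals ran from 35584931 to 52401153 counts. A gene without a count in a library has an upper limit of 3 counts there, which is 0.0573 to 0.0843 CPM (counts scaled to a common library size) at these depths. Intervals and limits of this kind cover counting error only, since molecular identifiers are not described. The 2 libraries of each pair within a group were compared by a chi-square over genes, and every pair differed by more than sampling noise (25.6 to 82.0 per gene). That does not show that the libraries came from separate animals. Each library was counted as 1 replicate because the labels give biological replicates.

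Genes were kept with filterByExpr, which left 16565 of the 20781 genes, and 4216 were not tested. Library sizes were scaled with TMM factors, which were 0.916 to 0.974 for vehicle and 1.05 to 1.08 for melatonin. Melatonin and vehicle libraries were compared across all genes with edgeR 4.0.16 by the robust quasi-likelihood F-test with group as the only term, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of F. CPM values used the TMM-scaled library sizes. Gene lists were compared with camera in the same fit, two-sided, with its preset correlation between genes of 0.01, and adjusted over the 57 lists with at least 3 tested members. For each list the members passing were also counted after adjustment over the list alone. Rotation tests (fry) and camera with a correlation estimated per list were run as alternatives.

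The groups, the comparison, the gene lists, the alternatives and the rule for naming genes were set before the data were examined. Genes are named by that rule as follows. The 10 higher and 10 lower genes with the largest fold change among those that passed had to have at least 10 counts on average and no overlap between groups. The 3 higher and 3 lower genes with the smallest p were added. From each list that passed, the 3 members with the smallest p that moved with the list were named, and from each other list described in detail, the 2 members with the smallest p. A fixed set (Mtnr1a, Mtnr1b, Nqo2, Pdgfra, Ly6a, Pparg, Cebpa, Fabp4, Adipoq, Plin1, Col1a1, Col3a1 and Acta2) was named whatever its result. The rule named 135 genes, of which 133 were tested. The melatonin receptor genes Mtnr1a and Mtnr1b were not analysed here. Some genes that the rule or a count would name are not reported here, although they stay in the counts and tests of their lists. Any other gene is said to have been chosen after its values were seen.

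The alternatives were DESeq2 1.42.0, limma-voom (limma 3.58.1), other scaling factors, no filter and a stricter filter on counts, a minimum fold, a stricter threshold, the replicate number as a block, and each library left out in turn. The statistical steps were tested on simulated counts for the 16565 genes, with 100 genes changed at each fold in 4 against 4 libraries. In that simulation of melatonin against vehicle, edgeR recovered 34% of genes changed by 1.5-fold and 67% of those changed by 2-fold, with 3 false calls, and made 0 calls when no gene was changed. DESeq2 recovered 52% and 76% with 34 false calls and limma-voom 30% and 67% with 3. DESeq2 made 10 calls and limma-voom 0 when no gene was changed. The simulation changed few genes and raised as many as it lowered. In the data 36.5% of the tested genes passed, and at least 2-fold differences were more often lower (1197) than higher (459). The recovery rates and false calls therefore need not hold for these data. Camera with either correlation and fry each called a simulated list of 28 genes raised by 1.5-fold and 0 of 56 random lists. The simulated genes were drawn independently of each other. The simulation therefore cannot show how often these tests call lists of correlated genes falsely. Other software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3 and bedtools 2.31.1.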

Results

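Gene expression was measured by bulk RNA sequencing in cultured mouse FAPs after 24 h with vehicle (4 libraries) or with melatonin (4 libraries), a hormone of the pineal gland that binds membrane receptors and also acts as an antioxidant. The question was which transcripts differ when these progenitors are exposed to melatonin in vitro. Total counts were 51037585, 45682034, 49822950 and 52401153 in vehicle replicates 1 to 4. Those of melatonin replicates 1 to 4 were 49202762, 40330511, 49769873 and 35584931. Genes encoded by the mitochondrial genome took 1.05% to 1.3% of the counts in the vehicle libraries and 2.09% to 2.44% in the melatonin libraries. Ribosomal protein genes took 4.06% to 4.64% with vehicle, 4.25% to 4.49% in melatonin replicates 1 to 3 and 5.83% in melatonin replicate 4. Below, log2 fold changes are melatonin over vehicle ± standard error, and levels are mean ± SD in CPM over n = 4 libraries, with vehicle first. Positions are those of whole protein-coding genes in GENCODE M21 on GRCm38.

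With melatonin, genes of adipocytes and of lipid storage were higher, and genes of inflammation, matrix, glycolysis and hypoxia were lower. The lists of these genes were called by camera at its preset correlation and lost the call with an estimated correlation (adjusted p = 0.054 to 0.068). The lipid droplet coat gene Plin1 went from 13.5 ± 2.21 to 184 ± 27.1 CPM, a 13.6-fold difference, and the adipokine gene Adipoq from 31.2 ± 1.6 to 133 ± 4.33 CPM. The cytokine gene Il1b went from 15.7 ± 5.32 to 0.239 ± 0.11 CPM, 64-fold lower, and the matrix protease gene Mmp3 from 2813 ± 653 to 61 ± 19.4 CPM, 46.1-fold lower. Col1a1, which encodes the main fibrillar collagen chain, went from 13770.0 ± 1328 to 6658 ± 387 CPM. In all, 6054 of 16565 tested genes (36.5%) passed at an edgeR adjusted p under 0.05, of which 2992 were higher and 3062 lower. At least 2-fold differences were more often lower (1197 genes) than higher (459), as were 8-fold differences (133 against 25). The 4 libraries of one group all lay above the 4 of the other for 5574 of the genes that passed, and for 6247 of all tested genes, where chance gives 2.86%.

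The split into higher and lower depends on scaling. With TMM factors 49.4% of the passing genes were higher, and with library totals alone 69.5% were (5099 higher and 2237 lower), because that scaling moves the median log2 fold change of all genes from 0.01 to 0.17. Changes below are relative to the TMM scaling. The first principal component (55.1% of variance) separated the groups, and on the second (14.4%) melatonin replicate 4 scored −54.4 while the other 3 melatonin libraries scored 18.5 to 25.5.

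**Figure D1:**
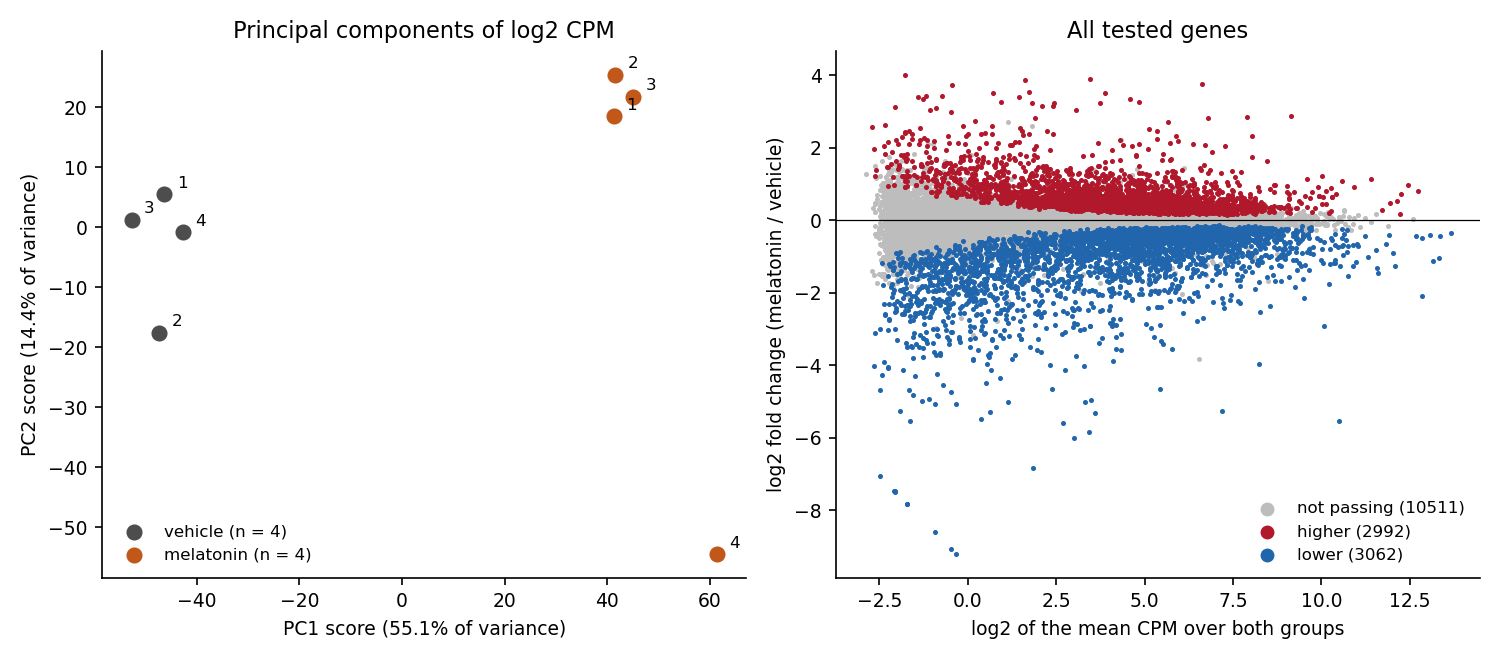
Left, scores of the 8 libraries on the first 2 principal components of log2 CPM (grey, vehicle; orange, melatonin; numbers are replicates), in which the groups lie apart on the first component and melatonin replicate 4 lies apart on the second. Right, log2 fold change (melatonin over vehicle) against log2 of the mean CPM for the 16565 tested genes, with 2992 higher in red, 3062 lower in blue and the others in grey. Of the tested genes, 9 have 0 counts in a whole group, and their fitted fold changes depend on the prior count.

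The largest increases were in genes of lipid metabolism and in several genes of low abundance. Thrsp, a regulator of lipogenesis, went from 1.36 ± 0.431 to 20.4 ± 2.71 CPM (3.90 ± 0.22), the glycerol channel gene Aqp7 from 0.387 ± 0.179 to 5.7 ± 0.785 CPM (3.87 ± 0.28), and Gpd1, which makes glycerol phosphate, from 2.36 ± 0.419 to 27 ± 4.24 CPM (3.51 ± 0.16). Mlxipl, encoding the carbohydrate response factor ChREBP, rose by a log2 fold change of 3.52 ± 0.31, the potassium channel gene Kcnk3 by 3.51 ± 0.37 and Fam222a by 3.39 ± 0.31. Sowahd rose by 4.01 ± 0.47 from 6 counts in all vehicle libraries to 103 with melatonin. Trim67 rose 10.7-fold, and 17.0-fold without vehicle replicate 3. Hpca rose 10.6-fold, and 20.9-fold without vehicle replicate 4. The smallest p-values among higher genes were those of Adipoq, Fabp4 and Cdo1, a cysteine dioxygenase gene, with edgeR adjusted p of 1.3e-07, 1.3e-07 and 2.7e-07, and Cdo1 went from 28 ± 2.15 to 195 ± 22.2 CPM.

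Among the largest decreases, 5 genes had 0 counts in all melatonin libraries. Against a limit of 3 counts over the group, Calb2, which encodes a calcium-binding protein, was at least 96.1-fold lower (294 vehicle counts), the collagenase gene Mmp1b, which has a close paralog, at least 89.3-fold, Spink6 at least 29.4-fold, and Ankk1 and the lactoferrin gene Ltf at least 28.8-fold each. Rp1 had 118 vehicle and 2 melatonin counts, a ratio of 57.9 with a counting interval of 15.7 to 484. Both of those counts came from melatonin replicate 2, and without it Rp1 was at least 29.8-fold lower. Il1a fell by 5.60 on the log2 scale (12.6 ± 4.42 to 0.251 ± 0.117 CPM), and Fabp7, a fatty acid binding protein gene, by 5.85 (21.2 ± 2.91 to 0.36 ± 0.0798 CPM). The smallest p-values among lower genes were those of Fabp7, the tetraspanin gene Tspan11 (34.5 ± 2.04 to 5.24 ± 0.319 CPM) and the decoy receptor gene Il13ra2 (21.7 ± 2.62 to 0.693 ± 0.149 CPM), with edgeR adjusted p of 1.3e-07, 1.3e-07 and 2.1e-07. Of the 133 genes named by rule and tested, 130 had no overlap between the groups. That count follows largely from the rule, which picks genes without overlap or with the smallest p, and is no separate evidence.

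Of 57 gene lists tested with camera, 9 were called higher and 18 lower (adjusted p under 0.05) at its preset correlation of 0.01. None held its call when the correlation was estimated for each list (0 of 57 at an adjusted p under 0.05, with 17 of the called lists at an unadjusted p under 0.05), and the rotation test fry called 42 lists. That adjusted p stands beside each called list below, and ranges over 14 alternatives refer to camera with the preset correlation. Counts of members adjusted over the list alone equalled those over all genes except where given, and members named because they ran against their list, or did not pass while nearly all others did, were chosen after their values were seen.

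**Figure D2:**
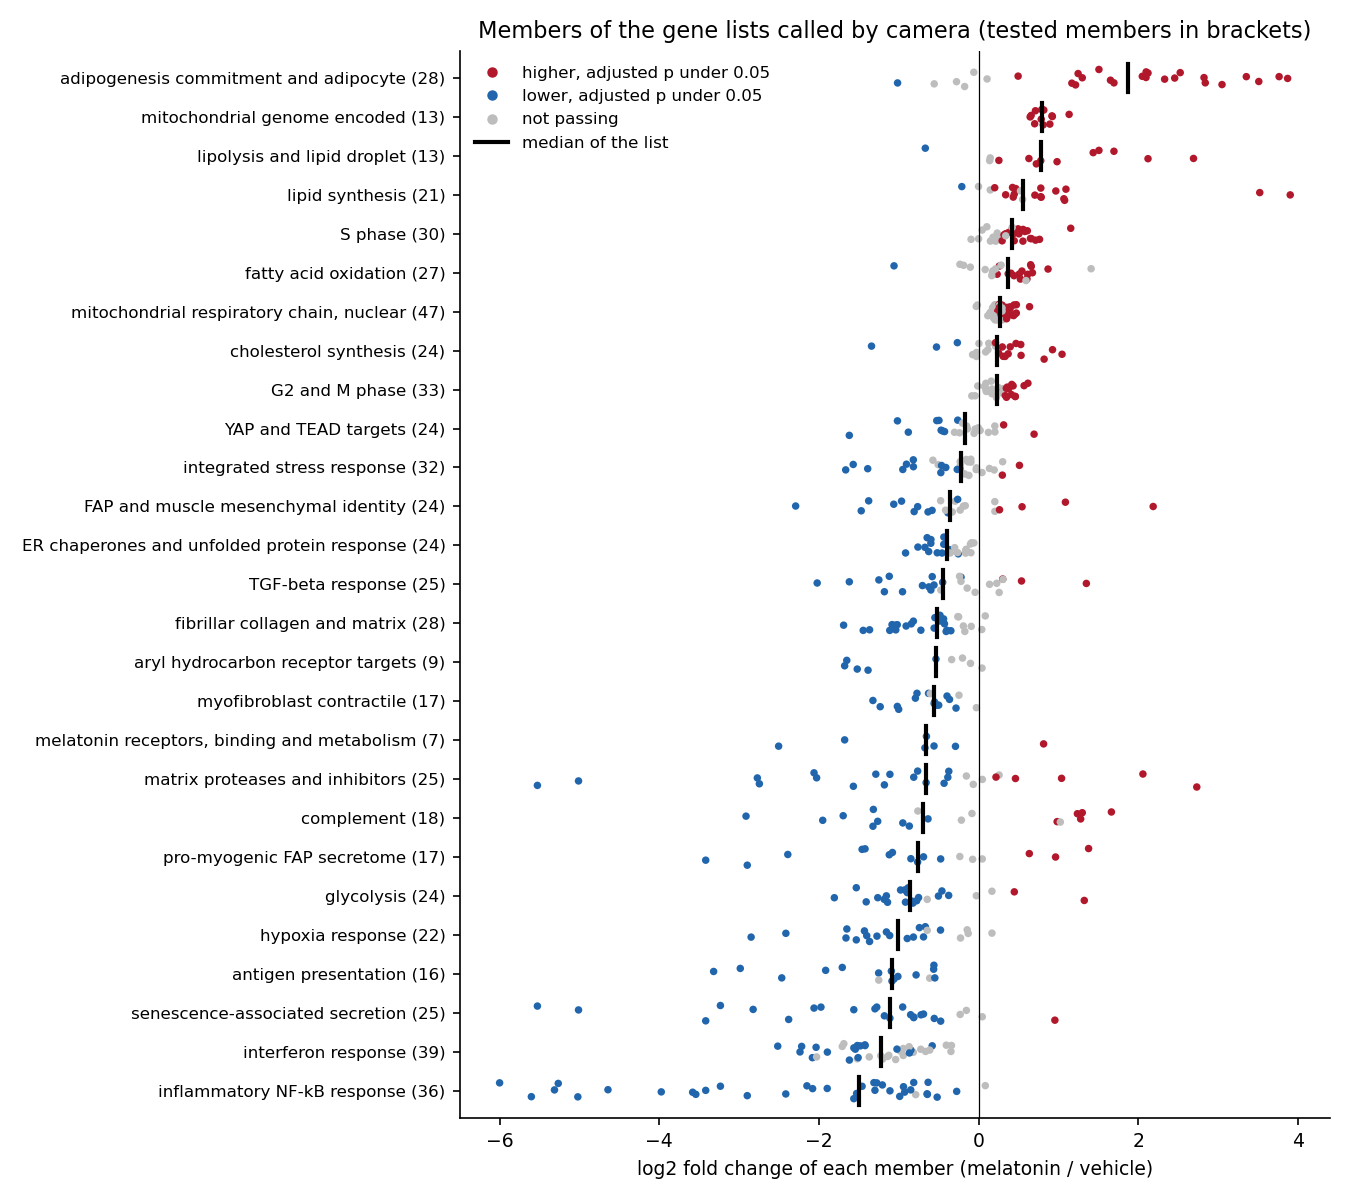
Log2 fold change (melatonin over vehicle) of every tested member of the 27 gene lists called by camera, 1 point per gene, with the number of tested members in brackets (red, higher; blue, lower; grey, not passing at an edgeR adjusted p under 0.05) and a black line at each list's median. Medians run from −1.49 in the inflammatory list to 1.87 in the adipocyte list.

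Adipocyte genes rose together. Of 28 tested members of the list of adipogenesis and adipocyte genes, 22 rose and 1 fell (adjusted over the list alone, 22 rose and 2 fell), with a median log2 fold change of 1.87 (camera adjusted p = 7.0e-40, and adjusted p = 0.054 with an estimated correlation). Pparg, the nuclear receptor gene that drives adipogenesis (ENSMUSG00000000440, chromosome 6, 115360951 to 115490399 on the plus strand of GRCm38), went from 10.9 ± 1.03 to 46.7 ± 4.63 CPM, and Cebpa, its partner transcription factor gene (ENSMUSG00000034957, chromosome 7, 35119293 to 35121928 on the plus strand), from 87.8 ± 10.4 to 442 ± 73.8 CPM. Fabp4, a fatty acid carrier gene of mature adipocytes (ENSMUSG00000062515, chromosome 3, 10204088 to 10208576 on the minus strand), rose by 2.84 ± 0.089, Plin1 (ENSMUSG00000030546, chromosome 7, 79720218 to 79732903 on the minus strand) by 3.76 ± 0.15 and Adipoq (ENSMUSG00000022878, chromosome 16, 23146536 to 23158028 on the plus strand) by 2.10 ± 0.063. Their edgeR adjusted p-values were 7.5e-07, 2.0e-06, 1.3e-07, 4.1e-07 and 1.3e-07. Cebpd, an early adipogenic factor gene, was the member that fell (-1.01).

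Genes of lipid handling followed. In the lipolysis and lipid droplet list, 10 of 13 members rose and 1 fell. The median was 0.78 (camera adjusted p = 3.5e-10, and adjusted p = 0.068 with an estimated correlation). The lipase genes Pnpla2 (53.2 ± 4.49 to 151 ± 5.85 CPM) and Lipe (2.12 ± 0.16) and the lipase inhibitor gene G0s2 (2.69 ± 0.12) rose, while Hilpda, a hypoxia-inducible droplet gene, fell (-0.67). Lipid synthesis had 16 of 21 members higher and 1, Me1, lower (-0.21), or 18 and 1 adjusted over the list alone, with a median of 0.55 (camera adjusted p = 4.0e-09, and adjusted p = 0.19 with an estimated correlation). The triglyceride synthesis gene Dgat1 rose by 1.07 ± 0.09 and the fatty acid elongase gene Elovl5 by 0.71 ± 0.06. In fatty acid oxidation, 15 of 27 members rose, among them Cpt2 (0.62 ± 0.061), Acadl (0.51 ± 0.055) and Acadm (0.66 ± 0.074), and Angptl4, a secreted lipase inhibitor gene, fell (-1.06). The median was 0.37 (camera adjusted p = 0.0010, and adjusted p = 0.25 with an estimated correlation). Cholesterol synthesis had 13 of 24 members higher, including Dhcr7 (1.05 ± 0.079), Nsdhl (0.82 ± 0.065) and Tm7sf2 (0.93 ± 0.098), and 3 lower, with a median of 0.23 (camera adjusted p = 0.012, and adjusted p = 0.38 with an estimated correlation). Among the lower ones were the sterol regulator gene Srebf2 (-0.27) and the sterol carrier gene Stard4 (-0.53).

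All 13 genes of the mitochondrial genome list rose, median 0.80 (camera adjusted p = 5.0e-12, and adjusted p = 0.15 with an estimated correlation), in the libraries whose share of mitochondrial genome counts was 2.09% to 2.44% against 1.05% to 1.3%. Examples are the respiratory complex subunit genes mt-Nd1 (862 ± 54.6 to 1599.8 ± 135 CPM), mt-Nd2 (1.13 ± 0.078) and mt-Nd4 (657 ± 65.9 to 1243 ± 114 CPM). Of 47 nuclear genes of the respiratory chain, 23 rose and 0 fell (31 and 0 adjusted over the list alone; 0 fell with DESeq2, limma-voom or at an unadjusted edgeR p under 0.05). The median was 0.27 (camera adjusted p = 1.2e-04, and adjusted p = 0.60 with an estimated correlation). Cyc1, the cytochrome c1 gene, rose by 0.64 ± 0.069, Ndufa10 by 0.47 ± 0.077 and Ndufb9 by 0.44 ± 0.08. Cell cycle genes rose as well. In the S phase list 19 of 30 members rose, median 0.42 (camera adjusted p = 2.2e-05, and adjusted p = 0.19 with an estimated correlation), including the replicative helicase genes Mcm2 (29.5 ± 1.02 to 45 ± 2.05 CPM) and Mcm7 (0.65 ± 0.07) and the uracil glycosylase gene Ung (1.15 ± 0.13). In the G2 and M phase list 13 of 33 rose, median 0.23 (camera adjusted p = 0.011, and adjusted p = 0.59 with an estimated correlation), including the cyclin genes Ccna2 (0.41 ± 0.088) and Ccnb2 (0.57 ± 0.12) and Cdc20 (0.38 ± 0.084). In either cell cycle list 0 members fell with edgeR, DESeq2, limma-voom or at an unadjusted edgeR p under 0.05.

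Inflammatory genes fell. Of 36 members of the NF-kB list, which holds cytokine, chemokine and feedback genes of that transcription factor, 34 fell and 0 rose (also 0 with DESeq2, limma-voom or at an unadjusted edgeR p under 0.05). The median was -1.49 (camera adjusted p = 3.2e-50, and adjusted p = 0.054 with an estimated correlation). The chemokine genes Ccl20 (82.9 ± 14.7 to 3.33 ± 0.59 CPM) and Cxcl5 (-1.53 ± 0.075) and the cyclooxygenase gene Ptgs2 (100.05 ± 16.2 to 8.6 ± 1.05 CPM) were the members with the smallest p. Il1b (ENSMUSG00000027398, chromosome 2, 129364570 to 129371139 on the minus strand) fell by 6.00 on the log2 scale (edgeR adjusted p = 6.2e-06). The 2 members that did not pass were Cxcl12 (0.08) and Il11 (-0.79). Of 25 genes secreted by senescent cells, 17 of which also stand in other lists, 21 fell and 1 rose. The median was -1.11 (camera adjusted p = 1.1e-19, and adjusted p = 0.054 with an estimated correlation). Cxcl1 (-1.56 ± 0.099) and Cxcl2 (-3.23 ± 0.16) fell, as did Mmp3 (ENSMUSG00000043613, chromosome 9, 7445822 to 7455975 on the plus strand, edgeR adjusted p = 3.3e-06), and Igfbp4, a growth factor binding protein gene, rose (0.96). The list of factors by which FAPs act on muscle stem cells had 11 of 17 members lower and 3 higher. The median was -0.76 (camera adjusted p = 2.9e-05, and adjusted p = 0.054 with an estimated correlation). The cytokine genes Il6 (84.2 ± 22.2 to 7.87 ± 1.42 CPM) and Lif (-2.90 ± 0.15) fell, and the growth factor genes Igf1 (0.64), Gdf10 (1.38) and Gdf11 (0.96) rose.

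Other immune lists fell as well. In the interferon list 18 of 39 members fell (20 adjusted over the list alone) and 0 rose (0 also with DESeq2, limma-voom or at an unadjusted edgeR p under 0.05). The median was -1.23 (camera adjusted p = 1.1e-05, and adjusted p = 0.59 with an estimated correlation). Examples are the antiviral gene Bst2 (584 ± 70.5 to 204 ± 72.6 CPM), Xaf1 (-1.51 ± 0.23) and the immunoproteasome gene Psmb8 (-1.42 ± 0.21). Antigen presentation had 14 of 16 members lower (15 adjusted over the list alone), median -1.09 (camera adjusted p = 7.8e-13, and adjusted p = 0.084 with an estimated correlation), with the class II genes Cd74 (15.4 ± 0.766 to 4.07 ± 0.503 CPM) and H2-Ab1 (-2.47 ± 0.16) and the class I gene H2-Q7 (-2.99 ± 0.18), whose reads can be split between close paralogs. Complement had 9 of 18 members lower and 5 higher (10 and 6 adjusted over the list alone), median -0.70 (camera adjusted p = 0.012, and adjusted p = 0.59 with an estimated correlation), and without melatonin replicate 4 the list was not called (camera adjusted p = 0.065, range 0.0023 to 0.065 over 14 alternatives). The alternative pathway gene Cfb (1901 ± 256 to 252 ± 79.5 CPM) and the inhibitor gene Serping1 (-0.87 ± 0.078) fell. The members that rose were C1qa (0.98), C1qb (1.24) and C1qc (1.28), which encode the chains of C1q, the terminal pathway gene C7 (1.66) and Cfd (1.299), a protease gene also made by adipocytes.

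Matrix and contractile genes were lower. Of 28 genes for fibrillar collagens and their matrix partners, 21 fell (22 adjusted over the list alone) and 0 rose (0 also with DESeq2, limma-voom or at an unadjusted edgeR p under 0.05). The median was -0.52 (camera adjusted p = 1.5e-12, and adjusted p = 0.054 with an estimated correlation). The thrombospondin gene Thbs1 (4574 ± 152 to 1679.7 ± 114 CPM), the collagen prolyl hydroxylase gene P4ha2 (-1.37 ± 0.071) and the crosslinking gene Loxl2 (-1.69 ± 0.10) fell. Col1a1 (ENSMUSG00000001506, chromosome 11, 94936224 to 94953042 on the plus strand) fell by 1.05 on the log2 scale and Col3a1 (ENSMUSG00000026043, chromosome 1, 45311538 to 45349706 on the plus strand) by 1.11 (edgeR adjusted p = 1.3e-05 and 2.3e-05). Matrix proteases and inhibitors had 16 of 25 members lower and 5 higher (16 and 6 adjusted over the list alone). The median was -0.66 (camera adjusted p = 5.6e-06, and adjusted p = 0.068 with an estimated correlation). Mmp9 (155 ± 10.4 to 22.7 ± 4.15 CPM) and the urokinase receptor gene Plaur (-2.03 ± 0.10) fell, while the proteases Mmp11 (2.06) and Adam12 (1.04) and the inhibitors Timp2 (0.46), Timp3 (0.22) and Timp4 (2.73) rose. Of 17 contractile genes of myofibroblasts, 14 fell, median -0.56 (camera adjusted p = 4.6e-05, and adjusted p = 0.19 with an estimated correlation), among them Actn1 (513 ± 20.6 to 256 ± 7.26 CPM), Tpm1 (-0.63 ± 0.055) and Flna (-0.50 ± 0.069). Acta2, the smooth muscle actin gene (ENSMUSG00000035783, chromosome 19, 34241090 to 34255590 on the minus strand), fell by 1.23 on the log2 scale (1049.5 ± 91.4 to 447 ± 130.4 CPM).

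**Figure D3:**
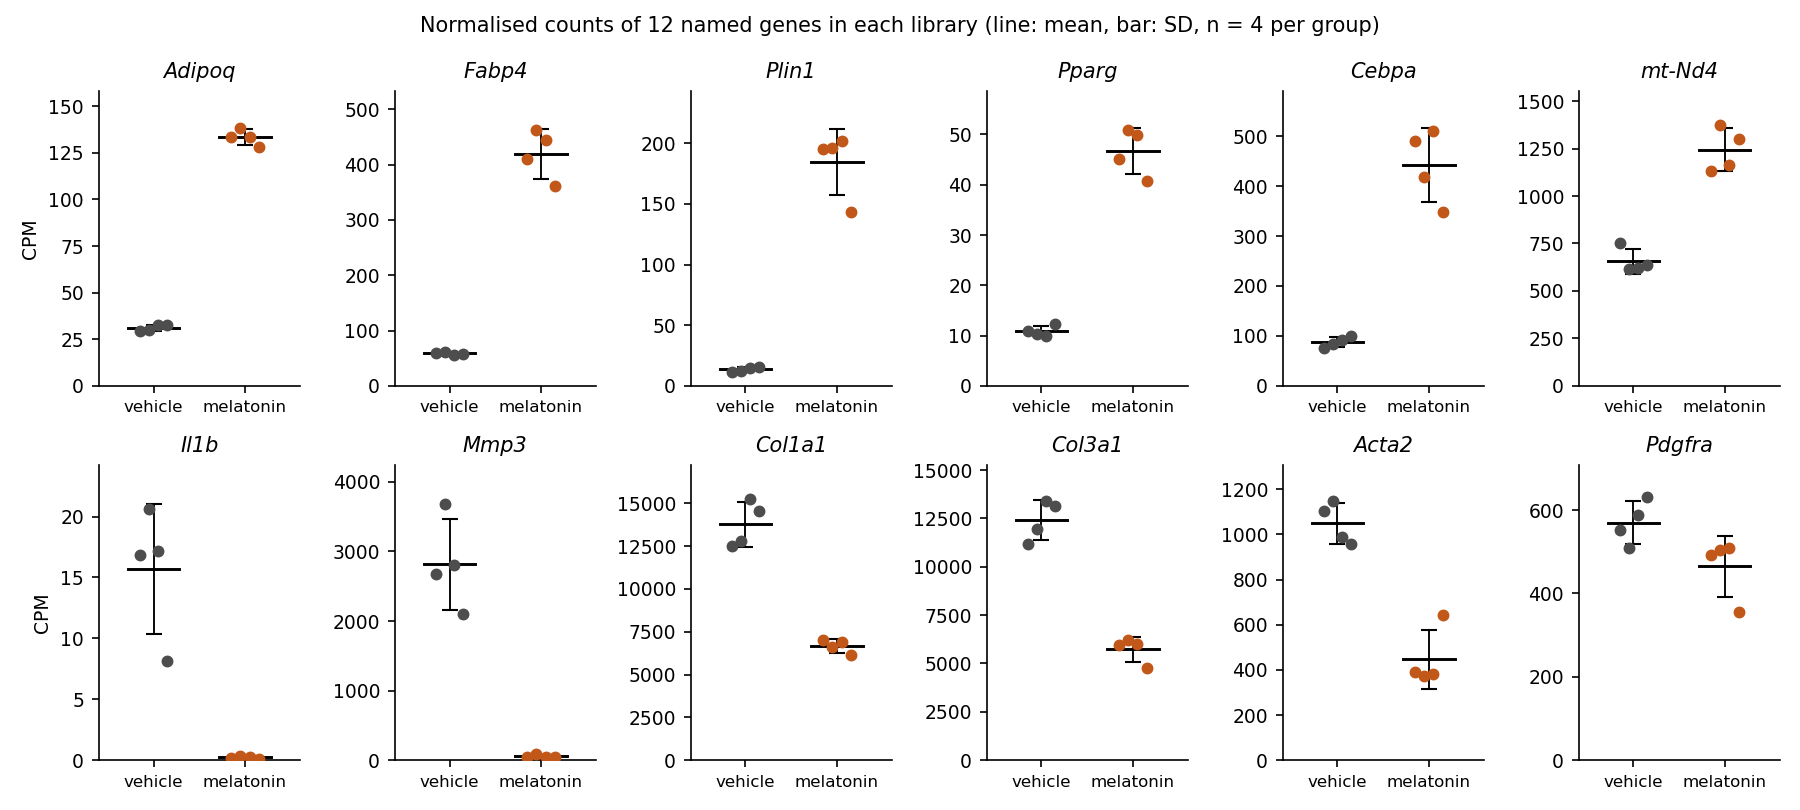
Normalised counts (CPM, linear axes from 0) of 12 named genes in each library, with a line at the mean and a bar of 1 SD, n = 4 per group (grey, vehicle; orange, melatonin). The groups do not overlap for the genes shown except Pdgfra, whose difference did not pass (edgeR adjusted p = 0.084).

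Growth factor pathways linked to the matrix moved the same way in part. The TGF-beta list had 13 of 25 members lower and 3 higher (13 and 4 adjusted over the list alone). The median was -0.45 (camera adjusted p = 0.0026, and adjusted p = 0.068 with an estimated correlation). Inhba, an activin subunit gene, fell (66.4 ± 3.89 to 16.3 ± 1.66 CPM), as did Ltbp2 (-1.25 ± 0.12) and the inhibitor gene Ldlrad4 (-0.95 ± 0.094), while Id1 (1.35), the inhibitory Smad gene Smad6 (0.54) and Tgfb3 (0.30) rose. Targets of YAP and TEAD had 9 of 24 members lower and 2, Nuak2 (0.31) and Wwc1 (0.70), higher (10 and 2 adjusted over the list alone). The median was -0.17 (camera adjusted p = 0.045, and adjusted p = 0.15 with an estimated correlation). Ccn2 (1082 ± 129 to 352 ± 109.6 CPM), Ccnd1 (-1.02 ± 0.094) and Axl (-0.88 ± 0.071) fell. The call of that list was lost with library totals (camera adjusted p = 0.11), with the replicate block (0.071), and without vehicle replicate 4 (0.062), melatonin replicate 1 (0.055) or melatonin replicate 2 (0.083), over a range of 0.019 to 0.11 in 14 alternatives.

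Markers of the FAPs themselves were mixed. In the list of FAP and mesenchymal identity genes 11 of 24 fell and 4 rose (13 and 4 adjusted over the list alone). The median was -0.36 (camera adjusted p = 0.0099, and adjusted p = 0.082 with an estimated correlation). The proteoglycan gene Dcn (911 ± 84.5 to 351 ± 42 CPM), Sema3c (-1.06 ± 0.085) and Smoc2 (-1.47 ± 0.13) fell, and Gsn (1.09), Col15a1 (2.19), Tcf7l2 (0.54) and Vim (0.26) rose. Pdgfra, the receptor gene used to define FAPs (ENSMUSG00000029231, chromosome 5, 75152292 to 75198215 on the plus strand), was at 569.6 ± 52.2 CPM with vehicle and 465 ± 74 CPM with melatonin and did not pass (-0.29 ± 0.12, edgeR adjusted p = 0.084). Ly6a, which encodes the surface marker Sca-1, fell by 0.58 on the log2 scale (336 ± 32.8 to 224 ± 21.8 CPM).

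Genes of glycolysis and hypoxia fell. Glycolysis had 19 of 24 members lower and 2, Ldhb (1.32) and Eno2 (0.45), higher. The median was -0.86 (camera adjusted p = 5.0e-12, and adjusted p = 0.059 with an estimated correlation). The enolase gene Eno1 (2783 ± 139 to 1262 ± 119 CPM) and the lactate dehydrogenase gene Ldha (2703 ± 226 to 1126 ± 119.8 CPM) fell, as did the pyruvate dehydrogenase kinase gene Pdk1 (-1.53 ± 0.074). Of 22 hypoxia-response genes, 11 of which also stand in other lists, 17 fell and 0 rose (0 also with DESeq2, limma-voom or at an unadjusted edgeR p under 0.05), median -1.004 (camera adjusted p = 1.2e-18, and adjusted p = 0.054 with an estimated correlation), with Egln3 (57.5 ± 4.76 to 10.8 ± 1.47 CPM) and Ero1l (-1.66 ± 0.084) as examples. Chaperones of the endoplasmic reticulum had 14 of 24 members lower (17 adjusted over the list alone), median -0.39 (camera adjusted p = 4.5e-05, and adjusted p = 0.14 with an estimated correlation), including Hsp90b1 (923 ± 55.5 to 489.9 ± 29.8 CPM), Creld2 (-0.62 ± 0.064) and Dnajc3 (-0.52 ± 0.054). In the integrated stress response 12 of 32 fell and 2 rose (12 and 3 adjusted over the list alone). The median was -0.22 (camera adjusted p = 0.0026, and adjusted p = 0.48 with an estimated correlation). Slc7a1 (-0.82 ± 0.063), the cystine transporter gene Slc7a11 (-1.57 ± 0.12) and Stc2 (-1.66 ± 0.12) fell, and the stress factor genes Ddit3 (0.51) and Sesn2 (0.30) rose.

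A list for melatonin receptors, binding and metabolism was set beforehand, and whether each member binds or metabolises melatonin was not tested here. Of its 7 tested members, 6 fell and 1, the nuclear receptor gene Rorb (0.81), rose. The median was -0.65 (camera adjusted p = 2.4e-04, and adjusted p = 0.054 with an estimated correlation). Cyp1b1, a cytochrome P450 gene, went from 632 ± 28.1 to 198 ± 7.65 CPM, the calcium-binding chaperone gene Calr from 2340.3 ± 141 to 1469 ± 104 CPM, and Nqo2, whose product binds melatonin, from 31.1 ± 2.42 to 21.1 ± 1.9 CPM. Targets of the aryl hydrocarbon receptor had 5 of 9 members lower, including Cyp1b1, Ahr itself (23.5 ± 1.57 to 9.02 ± 1.26 CPM) and Nfe2l2 (-0.53 ± 0.075). The median was -0.53 (camera adjusted p = 2.4e-04, and adjusted p = 0.068 with an estimated correlation). Of 22 clock genes, 9 fell and 2 rose, and the list was not called (camera adjusted p = 0.10, median -0.14), although Per2 (7.48 ± 0.597 to 1.95 ± 0.295 CPM) and Npas2 (13.1 ± 1.46 to 3.66 ± 0.351 CPM) fell.

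The antioxidant lists were not called. NRF2 targets had 12 of 27 members lower and 3 higher, median -0.23 (camera adjusted p = 0.0535), with the transporter gene Abcc1 lower (-1.02 ± 0.073) and Gsta4 higher (1.96 ± 0.12). That list passed without a count filter (camera adjusted p = 0.043), with a stricter filter (0.0491), and without vehicle replicate 1 (0.024) or melatonin replicate 4 (0.015), in a range of 0.015 to 0.15 over 14 alternatives. General antioxidant enzymes had 8 of 22 members lower and 7 higher (9 and 7 adjusted over the list alone), median -0.13 (camera adjusted p = 0.15), and the superoxide dismutase genes Sod2 (912 ± 61.2 to 402 ± 38.6 CPM) and Sod3 (1825 ± 139 to 543 ± 99.1 CPM) fell. In the autophagy and lysosome list 15 of 38 rose and 5 fell, median 0.14 (camera adjusted p = 0.086), with the lysosomal genes Mcoln1 (0.80 ± 0.062) and Neu1 (0.81 ± 0.073) higher. It passed with library totals (camera adjusted p = 0.012), without a count filter (0.043) and without melatonin replicate 3 (0.032), in a range of 0.012 to 0.13 over 14 alternatives.

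Several signalling lists held members that moved both ways and were not called. For the anti-adipogenic regulators, of 18 tested members, 7 rose and 4 fell, with a median of 0.19 and a camera adjusted p of 0.24 (adjusted over the list alone, 9 rose and 4 fell), and the Wnt modulator gene Dkk3 rose (137 ± 8.08 to 268 ± 14 CPM) while Dkk2 fell (-1.56 ± 0.13). For the Wnt response, of 26 tested members, 7 rose and 10 fell, with a median of -0.14 and a camera adjusted p of 0.52 (adjusted over the list alone, 10 rose and 10 fell), and the feedback inhibitor gene Nkd2 fell (-1.68 ± 0.087). In the BMP response, of 23 tested members, 8 rose and 7 fell, with a median of 0.14 and a camera adjusted p of 0.98, and the BMP antagonist gene Grem1 fell (-1.48 ± 0.073). For the Hedgehog response, of 14 tested members, 4 rose and 7 fell, with a median of -0.40 and a camera adjusted p of 0.14 (adjusted over the list alone, 4 rose and 8 fell), and the receptor gene Ptch1 (-1.49 ± 0.14) and Foxf1 (-1.47 ± 0.15) fell. For serum and immediate early genes, of 32 tested members, 5 rose and 15 fell, with a median of -0.28 and a camera adjusted p of 0.10 (adjusted over the list alone, 7 rose and 16 fell), with Fosl1 (-1.95 ± 0.095) and Nr4a2 (-1.33 ± 0.14) lower, and among 14 alternatives the list passed only without vehicle replicate 4 (camera adjusted p = 0.043, range 0.043 to 0.21). For thermogenic genes, of 10 tested members, 3 rose and 2 fell, with a median of 0.28 and a camera adjusted p of 0.26, with the cytochrome oxidase gene Cox8b higher (2.12 ± 0.21) and Tnfrsf9 lower (-3.11 ± 0.36). Signs of the median, the mean and the test differed for the anti-adipogenic and BMP lists.

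Markers of other cell types that a FAP culture can hold were compared in the same way, and none of these lists was called. For macrophages and monocytes, with 3 markers also in other lists, of 18 tested members, 5 rose and 3 fell, with a median of -0.10 and a camera adjusted p of 0.98, and the receptor gene Cd14 fell (57.6 ± 8.92 to 26.3 ± 3.25 CPM) while Ms4a7 rose (3.62 ± 0.366 to 6.56 ± 1.76 CPM). For satellite cells and myoblasts, with 3 markers also in other lists, of 14 tested members, 2 rose and 3 fell, with a median of 0.10 and a camera adjusted p of 0.41, and Calcr (33.1 ± 2.05 to 3.52 ± 0.869 CPM) and Sdc4 (-0.90 ± 0.092) fell. For endothelial cells, of 18 tested members, 2 rose and 4 fell, with a median of 0.0011 and a camera adjusted p of 0.99, with the receptor genes Flt1 lower (-2.09 ± 0.24) and Tek higher (17.1 ± 1.51 to 35.3 ± 3.61 CPM). For pericytes and smooth muscle, with 5 markers also in other lists, of 15 tested members, 2 rose and 7 fell, with a median of -0.25 and a camera adjusted p of 0.20, with Abcc9 higher (1.38 ± 0.20) and Acta2 lower. Signs of the median, the mean and the test differed for the satellite cell and endothelial lists.

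Muscle fibre genes varied between the melatonin libraries. For the myofibre markers, of 25 tested members, 1 rose and 0 fell, with a median of 0.51 and a camera adjusted p of 0.21, and 0 members passed adjusted over the list alone (4 higher at an unadjusted edgeR p under 0.05, 4 with DESeq2 and 1 with limma-voom, and 0 lower in each). Acta1, the skeletal muscle actin gene, was at 58.2, 44.4, 48.3 and 51.3 CPM with vehicle and at 127, 159, 108 and 47.9 CPM in melatonin replicates 1 to 4 (1.13 ± 0.32, edgeR adjusted p = 0.028). Its call was lost with the replicate block (edgeR adjusted p = 0.084) and without any one of vehicle replicates 1 to 4 or melatonin replicates 1 to 3 (0.05005 to 0.074). Mylpf, a fast muscle myosin light chain gene, was at 30.8, 30.6, 25.4 and 33.9 CPM with vehicle and at 67.6, 85.2, 52.5 and 25.1 CPM in melatonin replicates 1 to 4, and did not pass (0.93 ± 0.33, edgeR adjusted p = 0.0596). It passed with DESeq2 (adjusted p = 0.0052), with edgeR on library totals alone (adjusted p = 0.030) and without melatonin replicate 4 (log2 fold change 1.19, edgeR adjusted p = 9.8e-04), in a range of 9.8e-04 to 0.15 over its alternatives. Without that library the myofibre list was called higher (camera adjusted p = 1.2e-07, range 1.2e-07 to 0.56 over 14 alternatives). These values use the preset correlation of 0.01. Camera with an estimated correlation was run on all libraries only, where the estimate for this list was 0.90 and the camera adjusted p was 0.84.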

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

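In each group of 4 libraries, the library farthest from the rest was compared with the others by Dixon's ratio of its gap to the whole range, at the 95% critical value. Chance passes this limit in about 1 in 20 groups, and 23 of 267 groups did, where 13.3 would be expected. The library that stood apart was melatonin replicate 4 in 9 named genes, vehicle replicate 4 in 4, and vehicle replicates 1 and 3 and melatonin replicate 2 in 2 each, and vehicle replicate 2 and melatonin replicate 1 in 1 each.

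Melatonin replicate 4 had 5.831% of its counts in ribosomal protein genes, against 4.25% to 4.49% in the other melatonin libraries, and scored −54.41 on the second principal component, against 18.5 to 25.5. It was also the highest of the melatonin libraries for Acta2, at 642 CPM against 371 to 389.8, for Ccnb2 at 22.85 against 16.5 to 17.3, for Creld2 at 67.54 against 59.9 to 60.2, for Sdc4 at 143 against 121 to 123, and for Sod3 at 690.2 against 480.2 to 514. The same library was the lowest for Fabp7, at 0.2414 CPM against 0.387 to 0.411, for Foxf1 at 8.289 against 10.6 to 10.8, for Pdgfra at 354.3 against 491 to 509, and for Plin1 at 143.8 against 195 to 202.

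In the other melatonin libraries, Hpca was at 1.026 CPM in replicate 1, against 0.728 to 0.751 in the other 3. Mmp3 was at 90.12 CPM in replicate 2, against 50.8 to 52.1, and Rp1 at 0.04727 CPM in replicate 2, against 0 in the other 3.

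Among the vehicle libraries, replicate 4 was highest for Cd74 at 16.5 CPM against 14.9 to 15.1, for Cdc20 at 29.56 against 26.8 to 27.2, for Fam222a at 0.8622 against 0.302 to 0.395, and for Ung at 1.905 against 1.69 in the others. Vehicle replicate 3 was highest for Mmp9 at 170.7 CPM against 149 to 152 and for Ndufa10 at 70.08 against 60.8 to 62.0. Vehicle replicate 1 was highest for mt-Nd2 at 535.5 CPM against 467.5 to 471 and for mt-Nd4 at 755.2 against 618 to 637. Sowahd had 0 counts in vehicle replicate 2, against 0.0401 to 0.0438 CPM in the other 3, where it had 6 counts in all. Counting error alone could give that gap. It was not weighed for the other genes flagged here, of which Ung is also low in counts (329 over the vehicle libraries).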

How the results depend on the processing

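Every alternative was set before the data were examined, and a count is called the same when within 1.5 times. The 6054 genes changed became 6571 with DESeq2, 6097 with limma-voom, 5997 and 6083 with relative log expression and upper-quartile factors, 6009 without a count filter and 5511 with at least 50 counts on average, and no gene called in both was called in opposite directions. Library totals alone gave 7336, with 5099 higher because that scaling moves the median of all genes to 0.17. A fold of at least 2 left 1656 genes (459 higher, 1197 lower), a test against a minimum fold of 1.2 left 3500 (1455 higher, 2045 lower) and an adjusted p under 0.01 left 3865 (1754 higher, 2111 lower), as stricter rules must. Leaving out 1 library gave 5098 to 6566 genes, the highest without melatonin replicate 4 (2403 to 3284 higher, 2671 to 3282 lower) and 26 to 28 gene lists.

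With the replicate number as a block, 4942 genes and 26 lists were called. Deviations of same-numbered libraries correlated at 0.035, −0.046, −0.029 and 0.0043, and those of differently numbered libraries at −0.12 to 0.17. No pairing by number was seen in these values. A weak shared effect could look the same, so whether equal numbers share a mouse or a day was left open.

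Of the 27 lists called by camera, 0 were called with an estimated correlation (adjusted p 0.054 to 0.60), while fry called 42 lists for a direction and 54 for change either way, neither of which compares a list with other genes. The other scalings each called 27 lists, no filter 29 of 58 and the stricter filter 28 of 56. YAP and TEAD targets and complement lost their calls, and NRF2 targets, autophagy, immediate early and myofibre lists gained one, under the settings given beside them, and the causes were not tested. Among the 133 named genes, calls changed for Acta1 and Mylpf alone under the other tools, scalings and filters, the block and each library left out, and the minimum folds and the stricter threshold were not applied to them. The stricter filter tested 124 of them. The steadiness of the named genes follows largely from the rule, which picks genes with the smallest p or without overlap. It does not extend to all calls. Of the 6054 genes called, 6003 were called again with DESeq2 and 5229 with library totals alone. With the replicate block 4843 were, and without vehicle replicate 1, 4953 were. Depth limits the genes at 0 counts in one group, whose folds are bounds.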

Other observations

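Of the tests below, 2 were chosen only after the result was seen, namely that of a larger share of adipocytes and that of overlapping gene models. The levels given beside the macrophage test were also looked up afterwards.

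Further gene lists set before the data were examined were not called by camera. For mitochondrial dynamics and biogenesis, of 21 tested members, 10 rose and 1 fell, with a median of 0.17 and a camera adjusted p of 0.12. For basement membrane genes, of 16 tested members, 1 rose and 6 fell, with a median of -0.22 and a camera adjusted p of 0.27. For p53 targets and cell cycle arrest, of 22 tested members, 7 rose and 4 fell, with a median of -0.011 and a camera adjusted p of 0.29 (adjusted over the list alone, 7 rose and 5 fell). For apoptosis genes, of 22 tested members, 3 rose and 8 fell, with a median of -0.18 and a camera adjusted p of 0.22 (adjusted over the list alone, 4 rose and 9 fell). For the Notch response, of 17 tested members, 3 rose and 2 fell, with a median of 0.28 and a camera adjusted p of 0.63. For cytosolic chaperones, of 22 tested members, 5 rose and 4 fell, with a median of -0.0025 and a camera adjusted p of 0.82 (adjusted over the list alone, 6 rose and 4 fell). For glucocorticoid-responsive genes, of 18 tested members, 4 rose and 6 fell, with a median of -0.16 and a camera adjusted p of 0.41. For cAMP-responsive genes, of 23 tested members, 5 rose and 10 fell, with a median of -0.28 and a camera adjusted p of 0.22. For histone genes expressed in replication, of 18 tested members, 3 rose and 0 fell, with a median of 0.26 and a camera adjusted p of 0.21 (0 lower also at an unadjusted edgeR p under 0.05, with DESeq2 and with limma-voom).

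Ribosomal protein genes were near the median of all genes. For the large subunit, of 44 tested members, 1 rose and 0 fell, with a median of -0.019 and a camera adjusted p of 0.98 (adjusted over the list alone, 0 rose and 0 fell, with 1 member higher at an unadjusted edgeR p under 0.05, 1 each with DESeq2 and limma-voom, and 0 lower in each). For the small subunit, of 31 tested members, 0 rose and 0 fell, with a median of -0.005 and a camera adjusted p of 0.82 (1 member higher at an unadjusted edgeR p under 0.05, 1 with DESeq2 and 0 with limma-voom, and 0 lower in each). For markers of Schwann and neural cells, of 7 tested members, 2 rose and 0 fell, with a median of 0.54 and a camera adjusted p of 0.29 (adjusted over the list alone, 4 rose and 1 fell, and 1 lower at an unadjusted edgeR p under 0.05 and 0 with DESeq2 or limma-voom). For tenocyte and cartilage markers, of 12 tested members, 2 rose and 4 fell, with a median of -0.21 and a camera adjusted p of 0.54. For osteogenic markers, of 8 tested members, 2 rose and 2 fell, with a median of 0.069 and a camera adjusted p of 0.96 (adjusted over the list alone, 3 rose and 2 fell). For lymphocyte and granulocyte markers, of 4 tested members, 1 rose and 1 fell, with a median of 0.089 and a camera adjusted p of 0.74 (adjusted over the list alone, 2 rose and 2 fell). Erythroid markers had 1 tested member and were not tested as a list. Signs of the median, the mean and the test differed for the p53, both ribosomal, the lymphocyte and the osteogenic lists.

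Xist, a transcript of the inactive X chromosome, had 2001 to 7298 counts per library, although the labels give male mice. The Y-linked genes Ddx3y (322 to 734 counts), Kdm5d (204 to 407), Uty (109 to 265) and Eif2s3y (244 to 394) were counted in the same libraries. Rsad2, an interferon-induced gene, varied within groups, from 41.4 to 214 CPM of library totals with vehicle and from 8.63 to 63.4 with melatonin. These genes were chosen after their values were seen.

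Of the 35 ways to split the 8 libraries into 4 and 4, 1, the real one, gave 6054 genes, and the highest of the others gave 2. This argues against chance assignment of the libraries for this count, at the limit of 1 in 35 splits. The other splits mix both groups, so the group difference widens their spread and lowers their counts. A difference in preparation that follows the groups was not tested.

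The inflammatory list fell with a median of −1.49. Fewer macrophages in the melatonin cultures could lower such genes, but the macrophage and monocyte markers had a median of −0.10, and 3 of 18 fell. That median lies above −0.75, which is the inflammatory median divided by 2. The standard error of the mean over the 18 markers was 0.20, with the markers taken as independent, so it may be too small. The most abundant of these markers, Lyz2, Adgre1 and Cd14, were at 444, 61.5 and 57.6 CPM with vehicle and at 398, 50.7 and 26.3 CPM with melatonin, and of the 3 only Cd14 passed (edgeR), with Lyz2 and Adgre1 chosen after their values were seen. GC content or gene length could shift fold changes, but after removal of their trend over all genes the median was −1.31, from the 36 of 36 members with a GC value. These results argue against both as the whole cause. The macrophage markers moved both ways, however. Of the 18, 5 rose, among them C1qa, C1qb and C1qc (chosen after their values were seen), and 3 fell. In bulk libraries, lower inflammatory expression in FAPs cannot be told from lower expression in macrophages, and either remains a hypothesis.

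Adipocyte genes rose with a median of 1.87. Library scaling might produce a rise, and the lowest median under the other 3 scalings was 1.865. Those scalings put the median of all genes at 0.0054 to 0.17, so none of them could have removed a rise of this size. The comparison shows only that the rise does not hang on the choice among them. Removal of the GC and length trend left 1.96, which argues against that trend as the whole cause. A larger share of adipocytes with the same expression per cell would raise adipocyte genes by a common fold. The 22 members that rose instead spread from 0.50 to 3.87 around 2.0 (chi-square per degree of freedom 41.1, with 21 degrees), but genes that progenitors already express would rise less. That background was not measured, so a larger share and higher expression per cell cannot be told apart.

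Within a group, 33 genes had at least 200 counts in the highest library and a range of at least 30-fold. Among them, and chosen after their values were seen, Kctd12 had 0 counts in vehicle replicate 2 and 2220 to 6073 in the other libraries, and Gm45717 had 15 there and 15039 to 34479 elsewhere. Reads given to one or another of overlapping gene models may account for part of it, since 87.5% (28 of 32) overlap exons of another gene on the same strand, against 9.1% (1067 of 11765) of the other annotated genes with at least 200 counts in a library (Fisher's exact test, two-sided, p = 2.3e-25), and 96.9% against 37.8% on either strand (p = 1.7e-12). The sum of the protocadherin gamma genes, 4 of which are among the 33, ran from 246.3 to 1132 CPM. Its coefficient of variation over the 8 libraries was 31.7%, against 106% to 208% for those 4 genes. The sum was thus steadier, as a sum of several genes tends to be. Moving reads among the protocadherin genes alone would leave its remaining range unexplained. Of the 27 that were tested, 0 were called by edgeR (1 at an unadjusted p under 0.05, 1 with DESeq2, 2 with limma-voom), and no biological explanation was tested.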
